A study of Mus musculus with 6 samples.

How the data were processed

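RNA from the ventral dentate gyrus of male C57BL/6 mice was measured in 6 libraries, 3 from unstressed controls and 3 from animals given chronic restraint stress. Per the labels, the replicates are biological, the libraries were made with a stranded total RNA kit after removal of ribosomal RNA, and all were sequenced in one pool over several lanes as single-end reads. The labels do not say whether a library holds 1 animal or several, so p-values of genes measure the spread between these samples.

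The deposited values are whole-number counts per gene symbol, 1 file per library, with 24062 symbols. The submitters' processing notes name FastQC 0.11.3, Trimmomatic 0.33, TopHat2 2.0.9, HTSeq 0.6.1 and edgeR 3.12.0 and the builds mm10 and GRCm38, without role or order. The annotation, the counting options and the strand setting are not given in the sources used here, so reads of overlapping antisense genes may be shared with the genes they overlap. Per the values of the deposited files, rows in HTSeq's summary format hold reads assigned to no gene, which made up 59.5% to 63.1% of the reads listed per library, and ambiguous reads, which made up 0.211% to 0.253%. These rows were left out of library sizes and tests.

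Gene counts summed to between 8305753 and 10107953 per library. A count of 0 allows up to 3 counts, which is 0.297 to 0.361 CPM per library, where CPM puts library counts on a common total. This limit covers counting error only. No pair of libraries agreed within sampling noise. The lowest chi-square per degree of freedom over genes was 3.09, between stress replicates 2 and 3.

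All tests were run in R 4.3.3. Genes were kept by the default filter of edgeR 4.0.16 (filterByExpr), which left 14058, and libraries were scaled by trimmed mean of M values (TMM). Stress was compared with control by edgeR's quasi-likelihood F-test with group as the single term, two-sided. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. Standard errors (SE) of log2 fold changes come from a limma 3.58.1 voom fit of the same design. CPM values are scaled by TMM and given as mean ± SD over 3 libraries.

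43 gene lists of pathways, RNA quality and cell types were fixed before the data were examined. The 41 with at least 5 tested members were tested with camera on the edgeR fit, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera compares the members with the other tested genes, and at this preset it takes them as nearly independent of each other. Unless another test is named, adjusted p-values of genes come from edgeR's quasi-likelihood test and those of lists from camera. Members past the threshold were counted over all tested genes and adjusted over the list alone. The named genes followed a rule fixed before the data were examined. It takes the 12 genes with the largest log2 fold change in each direction among those past the threshold with an average log2 CPM of at least 1 and no overlap between the groups, leaving out clone, predicted, microRNA, small nucleolar RNA and pseudogene names. Where fewer than 5 genes of a direction pass, it takes the 8 with the smallest p. It adds Slc7a11, Grm2, Slc1a2, Slc1a3, Nr3c1, Nr3c2, Fkbp5, Bdnf and Grm5, and up to 4 members with the smallest p from each list that passes or has members past the threshold. Genes named outside this rule are said to be. Some genes that the rule takes are not reported here.

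Positions were taken from GENCODE release M21 on GRCm38, the build that the submitters' notes name, by matching symbols. 22708 of the 24062 symbols, or 94.4%, matched exactly 1 gene.

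The fits were tested on simulated counts drawn 5 times for the 14058 genes at the observed means, library sizes and dispersions, with 200 genes changed in each draw. For stress against control, 45.7% of genes changed 1.5-fold, 78.5% of those changed 2-fold and 97.0% of those changed 4-fold were called, all in the right direction. 2 lists were also shifted in the same draws. Of the calls without those of their members, 6.48% were of unchanged genes. A shift of 0.5 on the log2 scale in the astrocyte list was called in 5 of 5 draws. The same shift in the choroid plexus list, whose members vary far more between these libraries, was called in 2 of 5, and 1 other list was called over the 5 draws. Each gene was drawn independently, so members of a list were not correlated in these draws. The draws therefore do not show how often lists pass when members move together. The changed genes were drawn from those above a minimum mean count. The shares called hold for 200 changed genes, and with fewer the adjusted threshold would be stricter.

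Alternatives chosen before the data were examined were relative log expression and upper-quartile scaling, no filter, a filter of CPM of at least 1 in at least 3 libraries, DESeq2 1.42.0, limma-voom, edgeR's exact test, a robust fit, a threshold of 0.10, the replicate number as a block, and each library left out in turn. For lists, an estimated correlation, fry and camera on log2 CPM with a prior count of 2 were added. After the data had been seen, limma-voom with sample quality weights, an offset for GC content and transcript length, and list tests without stress replicate 1 under an estimated correlation or fry were added.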

Results

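The dentate gyrus is the entry region of the hippocampus, and its ventral part is often studied in relation to stress and emotion. Transcript levels were measured there in 3 control libraries and in 3 libraries from mice given chronic restraint stress, a repeated confinement that acts as a psychological stressor. Control libraries held 8305753, 10107953 and 9329719 gene counts, and stress libraries 9351979, 8575540 and 9626686. The series asks about the glial cystine/glutamate exchanger xCT, the product of Slc7a11, in resilience to stress. The comparison available for this is stress against control.

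4 genes were lower in stress and 0 were higher. Ddit4l, whose product restrains mTOR signalling, fell from 24.5 ± 1.37 to 8.65 ± 1.61 CPM (SD, n = 3), a log2 fold change of -1.51 (SE 0.14). Tacr3, the receptor for neurokinin B, fell from 8.12 ± 0.456 to 2.58 ± 0.350 CPM, a log2 fold change of -1.65 (SE 0.19). Igfbp6, a binding protein for insulin-like growth factors, fell from 13.8 ± 1.80 to 5.38 ± 0.258 CPM, a log2 fold change of -1.36 (SE 0.16). Kcns1, a modulatory subunit of voltage-gated potassium channels, fell from 14.2 ± 1.37 to 5.80 ± 0.329 CPM, a log2 fold change of -1.29 (SE 0.15). All 3 stress libraries lay below all 3 controls for each of these genes, and the adjusted p was 0.0456 for each by edgeR's quasi-likelihood test. Ddit4l lies on chromosome 3 from 137621612 to 137628333 and Tacr3 on chromosome 3 from 134829007 to 134934579. Igfbp6 lies on chromosome 15 from 102144362 to 102149511 and Kcns1 on chromosome 2 from 164163619 to 164171113. All 4 are annotated as protein-coding genes. At an unadjusted p under 0.05 the same test gave 1225 genes, 543 of them higher and 682 lower, where chance gives 702.9. DESeq2 called 38 higher and 68 lower, edgeR's exact test 43 and 86, and limma-voom 0 and 1. Without any 1 control library, or without stress replicate 3, edgeR's quasi-likelihood test called 0 genes, and without stress replicate 2 it called 2 higher and 26 lower. The groups did not overlap for 2053 of the 14058 tested genes, or 14.6%, where chance gives 10%.

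**Figure D1:**
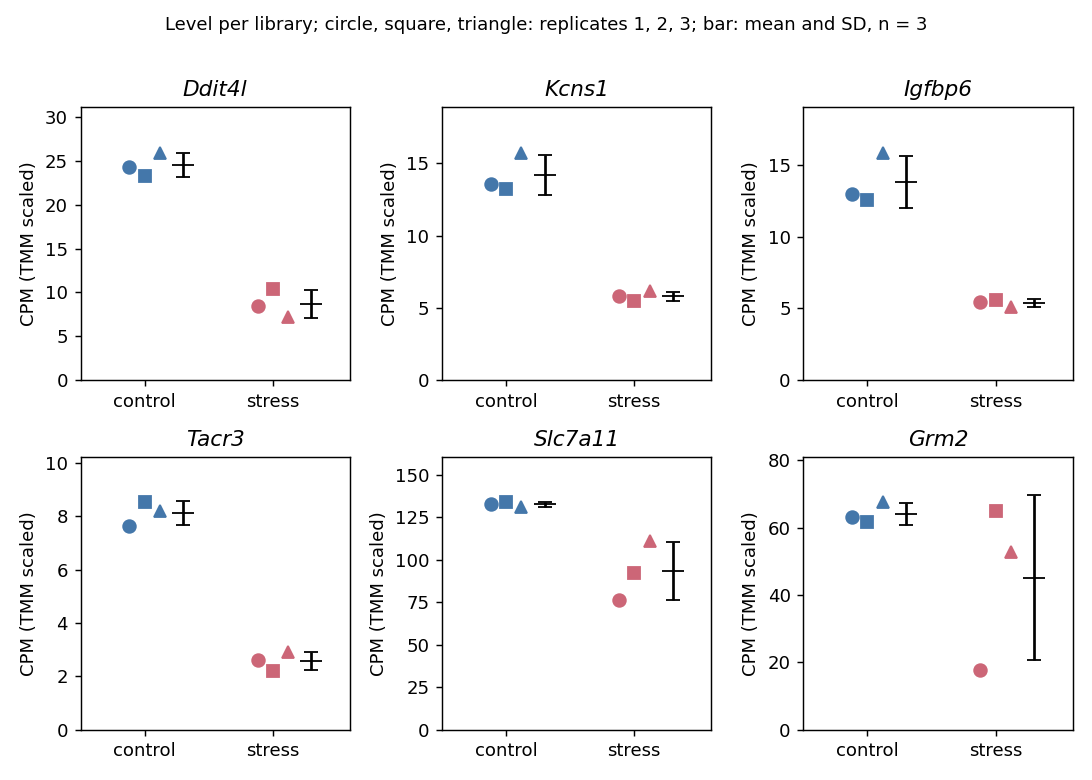
Level of 6 genes in each library, in CPM on a linear axis from 0, with controls in blue, stress in red, a marker shape for each replicate number, and the mean and SD of 3 libraries beside them. Ddit4l, Kcns1, Igfbp6 and Tacr3 separated the groups, Slc7a11 ranged from 76.5 to 111 CPM in stress, and Grm2 was at 17.7 CPM in stress replicate 1 against 52.7 to 67.6 CPM in the other libraries.

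Of the next genes by p, none passed. On the lower side these were the cadherin gene Cdh20 with a log2 fold change of -0.94 (SE 0.13), Myoc with -1.07 (SE 0.16), the nuclear receptor gene Rora with -0.63 (SE 0.09) and Mab21l1 with -3.40 (SE 0.53). Mab21l1 averaged 0.367 ± 0.131 CPM in stress, near the level that 3 counts give, and lies within Nbea on the opposite strand. Their adjusted p-values ran from 0.151 to 0.196. On the higher side the 8 genes with the smallest p had adjusted p-values from 0.199 to 0.215. They were Adra1d, an alpha-1 adrenergic receptor, at 0.81 (SE 0.14), the cyclin gene Ccnd1 at 0.62 (SE 0.12), Lmo1 at 0.64 (SE 0.12), Mdga1 at 0.55 (SE 0.10), Mmd at 0.45 (SE 0.09), the DNA repair enzyme gene Parp1 at 0.32 (SE 0.06), and the clone-named 9530059O14Rik at 0.54 (SE 0.10) and 6330403A02Rik at 0.64 (SE 0.12). For these 8, each stress library lay above each control.

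Slc7a11, on chromosome 3 from 49892526 to 50443614 and overlapped on the opposite strand by Gm37854, was measured at 132 ± 1.32 CPM in controls and 93.1 ± 17.1 CPM in stress. Its log2 fold change was -0.51 (SE 0.12), with all 3 stress libraries below all 3 controls, and the adjusted p of 0.268 did not pass. DESeq2 gave an adjusted p of 0.0246 and edgeR's exact test 0.0208, while the alternatives ran from 0.0208 to 0.770. Without stress replicate 1 the log2 fold change was -0.38 (SE 0.08), with an adjusted p of 0.0807. Slc3a2, the partner subunit of xCT, named here after its value was seen, had a log2 fold change of -0.06 (SE 0.07). The astroglial glutamate transporter genes Slc1a2 and Slc1a3 had log2 fold changes of -0.18 (SE 0.08) and -0.15 (SE 0.09), and neither passed. Without stress replicate 1 these were -0.12 and -0.064.

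The list of glutamate transport and metabolism genes moved down by camera, with an adjusted p of 0.0135, a median log2 fold change of -0.09 and 14 of its 20 tested members negative. With an estimated correlation the call was lost, with an adjusted p of 0.567. By fry, which asks if the members move one way on balance, the adjusted p was 0.00207. The camera call was also lost without control replicate 2, with an adjusted p of 0.0501, and the median was -0.14 without stress replicate 3. None of its members passed over all genes. 1 rose and 4 fell when adjusted over the list alone. The vesicular transporter gene Slc17a7 had a log2 fold change of 0.28 (SE 0.07), against -1.41 (SE 0.38) for the vesicular transporter gene Slc17a6 and -0.34 (SE 0.08) for the amino acid transporter gene Slc38a1. The 10 tested metabotropic glutamate receptor genes did not pass as a list, with a median of -0.20 and an adjusted p of 0.0941. Without stress replicate 2 the list passed downward, with a median of -0.24 and an adjusted p of 0.0148, and without stress replicate 1 its median was -0.12. Grm2, which encodes mGlu2 and lies on chromosome 9 from 106643095 to 106656082, was at 64.1 ± 3.122 CPM in controls and 45.1 ± 24.5 CPM in stress. Its log2 fold change of -0.51 (SE 0.38) was -0.13 (SE 0.10) without stress replicate 1 and -0.86 without stress replicate 2. Grm5, for mGlu5, had a log2 fold change of 0.13 (SE 0.10), which was 0.064 without control replicate 1, 0.22 without stress replicate 1 and 0.077 without stress replicate 3.

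Genes of the corticosteroid response did not pass. The mineralocorticoid receptor gene Nr3c2 had a log2 fold change of 0.36 (SE 0.10) and the glucocorticoid receptor gene Nr3c1 -0.16 (SE 0.07), with adjusted p-values of 0.357 and 0.541. Fkbp5, a co-chaperone gene induced by glucocorticoids, had a log2 fold change of 0.13 (SE 0.07), and the neurotrophin gene Bdnf 0.19 (SE 0.09). The 28 tested glucocorticoid-responsive genes had an adjusted p of 0.717 as a list, and the 21 tested inflammatory and NF-kB genes 0.898.

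Of the 41 lists, 14 passed, 6 down and 8 up, and none passed with an estimated correlation. No member of any list passed over all tested genes. The list of circadian clock genes moved down with a median log2 fold change of -0.17 and 17 of 19 members negative, with an adjusted p of 4.64e-06, and 0.567 with an estimated correlation. 2 of its members fell and 0 rose when adjusted over the list alone. Rora and the clock repressor gene Nr1d2 had log2 fold changes of -0.63 and -0.31 (SE 0.06), Hlf -0.62 (SE 0.19) and Rorb -0.35 (SE 0.11). Rora is also in the thalamus and habenula list and Rorb in the neocortical and entorhinal list, so these lists are not independent of each other. Hlf was at -0.39 without stress replicate 1, where its level was 84.8 CPM, against 156 and 143 CPM in the other stress libraries. The astrocyte list moved down with a median of -0.16 and 19 of 22 members negative, with an adjusted p of 6.03e-06, and 0.832 with an estimated correlation. Its median was -0.11 without control replicate 2. The list's level, as median log2 CPM relative to the controls, was 0.066, 0.061 and -0.121 in control replicates 1, 2 and 3. In stress replicates 1, 2 and 3 it was -0.188, -0.134 and -0.124, so control replicate 3 lay close to the last 2. Adjusted over the list alone, 1 fell, and the connexin gene Gjb6 had -0.43 (SE 0.10), F3 -0.31 (SE 0.08) and Fgfr3 -0.21 (SE 0.07).

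Lists of other cell types and regions moved down as well. Thalamus and habenula genes had a median of -0.32, with 12 of 14 members negative and an adjusted p of 4.64e-06, and 0.567 with an estimated correlation. The median was -0.18 without stress replicate 3, whose level of -0.59 was the lowest, against -0.22 and -0.31 in stress replicates 1 and 2. Adjusted over the list alone, 2 of its members fell. Slc17a6 and Rora, which other lists also hold, led it, followed by Lef1 at -0.66 (SE 0.21) and Nwd2 at -0.34 (SE 0.12). Meningeal and perivascular fibroblast genes had a median of -0.34 and an adjusted p of 0.000200, and 0.832 with an estimated correlation, and the median was -0.20 without control replicate 1. The list's level was 0.115, -0.196 and 0.112 in control replicates 1, 2 and 3. In stress replicates 1, 2 and 3 it was -0.462, -0.472 and -0.212, so control replicate 2 lay close to stress replicate 3. Adjusted over the list alone, 3 of the 18 fell. The collagen gene Col1a2 was at -0.55 (SE 0.15), Aldh1a2 at -0.76 (SE 0.21), Slc13a3 at -0.49 (SE 0.14) and Fmod at -1.67 (SE 0.66). For Fmod the groups overlapped. Neocortical and entorhinal genes had a median of -0.17 and an adjusted p of 0.0182, and 0.832 with an estimated correlation. 3 of the 18 fell and 1 rose when adjusted over the list alone. Cux2 was at -0.88 (SE 0.18) and Rasgrf2 at -0.34 (SE 0.10), while Crym was at 0.61 (SE 0.16). Without stress replicate 1 this list did not pass, with an adjusted p of 0.835, and without stress replicate 2 its median was -0.38.

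5 of the 8 lists that moved up belong to other cell types, and these followed stress replicate 1. Choroid plexus genes had a median log2 fold change of 2.14, which was -0.083 without that library. Ttr, the transthyretin gene of choroid plexus epithelium, was at 4258 CPM in stress replicate 1 and between 2.08 and 6.52 CPM in the other 5 libraries. Kl was at 199.5 CPM there against 17.6 to 23.6 CPM, F5 at 97.7 against 0.484 to 1.27 CPM and Col8a1 at 39.8 against 1.04 to 1.81 CPM. Ependymal genes had a median of 1.40 and -0.049 without that library, and Dnah6, Foxj1, Hydin and Rsph1 were each highest in it, at 38.1, 18.9, 14.2 and 6.55 CPM. Striatum and amygdala genes had a median of 0.95 and 0.057 without it. The opioid peptide gene Penk was at 169 CPM there against 6.81 to 10.8 CPM, and the adenosine receptor gene Adora2a at 40.8 against 0.931 to 1.69 CPM. Foxp1 was at 129 CPM there against 71.2 to 91.5 CPM, while Dlk1 was highest in stress replicate 3, at 5.19 CPM. CA3 pyramidal genes had a median of 0.33 and -0.027 without that library, with Cdh24 at 0.68 (SE 0.21), Nptx1 at 0.33 (SE 0.11), Sv2b at 0.40 (SE 0.17) and Pvrl3 at 0.93 (SE 0.49), of which Sv2b was at 0.17 and Pvrl3 at 0.12 without it. Myelin and oligodendrocyte genes had a median of 0.26 and -0.080 without it, with Mobp at 0.36 (SE 0.29), Cldn11 at 0.31 (SE 0.27), Fa2h at 0.28 (SE 0.25) and Enpp6 at 0.43 (SE 0.40). Without it these 4 were at -0.079, -0.080, 0.19 and 0.069, and without stress replicate 3 at 0.63, 0.57, 0.50 and 0.78. Without control replicate 1 Fa2h was at 0.12 and Enpp6 at 0.29, and Fa2h was at 0.47 without control replicate 2 and 0.13 without stress replicate 2. The camera adjusted p-values of these 5 lists were 0.000800, 0.00602, 0.000200, 0.00602 and 0.0211 in the order given, and 0.832 for each with an estimated correlation. None of the 5 passed without stress replicate 1. The CA3 call was also lost without control replicate 2, with an adjusted p of 0.0763, and the oligodendrocyte call without control replicate 1, control replicate 3 or stress replicate 2, with 0.345, 0.0970 and 0.0502. The CA3 median was 0.50 without stress replicate 2, and the oligodendrocyte median 0.15 without control replicate 1 and 0.50 without stress replicate 3.

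**Figure D2:**
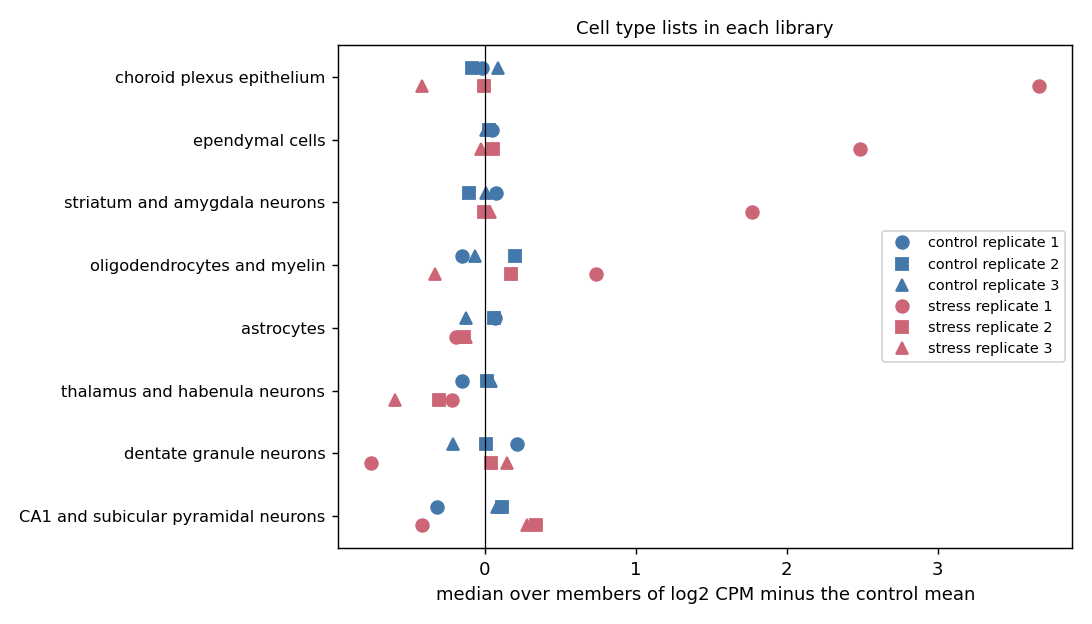
Level of 8 cell type lists in each library, as the median over members of log2 CPM minus the mean of the controls, with controls in blue, stress in red and a marker shape for each replicate number. Stress replicate 1 was at 3.67 for choroid plexus, 2.49 for ependymal and 1.77 for striatum and amygdala genes, and at -0.75 for dentate granule neuron genes.

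Immediate-early genes, which neuronal activity induces, moved up with a median log2 fold change of 0.14 and an adjusted p of 0.0135, and 0.832 with an estimated correlation. Adjusted over the list alone, none of the 29 members passed. Nptx2 was at 0.68 (SE 0.18), Egr4 at 0.62 (SE 0.24), Dusp6 at 0.49 (SE 0.14) and Nr4a3 at 0.49 (SE 0.17). The list's level was -0.22 in stress replicate 1 and 0.51 and 0.04 in stress replicates 2 and 3, against -0.05, -0.03 and 0.14 in controls. Without stress replicate 2 the list's median turned to -0.076 and the call was lost, with an adjusted p of 0.967, and it was also lost without control replicate 2, with 0.0763. The median was 0.21 without stress replicate 3. Postsynaptic density and spine genes moved up with a median of 0.10 and 19 of 24 members positive, with an adjusted p of 0.0135, and 0.832 with an estimated correlation. The call was lost without control replicate 2, control replicate 3 or stress replicate 2, with adjusted p-values of 0.0763, 0.0970 and 0.0813, and the median was 0.15 without control replicate 1. Dlgap3 was at 0.25 (SE 0.07), Ppp1r9b at 0.21 (SE 0.07) and Baiap2 at 0.20 (SE 0.07), while the scaffold gene Dlg1 was at -0.34 (SE 0.09). Heat shock and unfolded protein genes moved up with a median of 0.09 and an adjusted p of 0.0211, and 0.832 with an estimated correlation. Hspa1a was at 0.53 (SE 0.19) and Hspa1b at 0.68 (SE 0.29), a near-identical pair whose counts are uncertain, with Creld2 at 0.33 (SE 0.18) and Hspe1 at 0.23 (SE 0.12). 21 of the 28 members were highest in stress replicate 1, and the median without it was -0.020, with an adjusted p of 0.967. Hspa1b, Creld2 and Hspe1 were then at 0.41, 0.16 and 0.10. The call was also lost without control replicate 2 or 3, with 0.0663 and 0.124, and the median was 0.15 without stress replicate 3. No member of the postsynaptic or heat shock lists passed when adjusted over the list alone. Among the 20 lists not described one by one, adjusted p-values ran from 0.0571 to 0.998, and 6 of the 20 passed in a fit with 1 library left out.

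Without stress replicate 1, edgeR's quasi-likelihood test called 11 genes higher and 30 lower, the 4 genes above among them. Named here by the same rule in that fit, the genes higher included Nptx2, a neuronal pentraxin, at a log2 fold change of 0.82 (SE 0.14), the scaffold kinase gene Ksr1 at 0.62 (SE 0.09), the receptor auxiliary subunit gene Cacng8 at 0.60 (SE 0.10) and the transcription factor gene Bcl11b at 0.50 (SE 0.07). Bcl11b was at 149 CPM in stress replicate 1, below the 162 to 181 CPM of the controls, and at 0.31 with all 6 libraries. The genes lower included Slc17a6 at -1.03 (SE 0.14), Vwc2l at -1.13 (SE 0.14) and Ptgds, for prostaglandin D synthase, at -1.38 (SE 0.23), whose 169 CPM in stress replicate 1 lay within the 151 to 290 CPM of the controls. The common coefficient of biological variation was 12.01% with 6 libraries and 7.13% without that library. For 26 of the 30 genes lower, stress replicate 1 also lay below all controls, and for 6 of the 11 higher it also lay above them. The share of all tested genes on these sides in stress replicate 1 was not computed. The counts therefore do not show support from that library.

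11 lists passed without stress replicate 1, 6 up and 5 down, and 7 of them had passed in the same direction with all 6 libraries. These 7 were the thalamus and habenula, clock, astrocyte, fibroblast, glutamate transport, immediate-early and postsynaptic lists. With an estimated correlation none of the 7 passed, with an adjusted p of 0.638 for the thalamus and habenula and glutamate transport lists and 0.711 for the other 5. Immediate-early genes then had a median of 0.30 and an adjusted p of 4.25e-08 at the preset correlation, while the call with all 6 libraries was lost without stress replicate 2. CA1 and subicular genes had a median of 0.25 and an adjusted p of 0.00413, dentate granule genes 0.10 and 0.0377, ionotropic glutamate receptor genes 0.08 and 0.0377, and ventral hippocampal pole genes 0.03 and 0.0320. With an estimated correlation the adjusted p-values of these 4 lists were 0.711, 0.909, 0.711 and 0.717. Granule levels of 0.042 and 0.147 in stress replicates 2 and 3 lay within the controls' -0.21 to 0.22. Ventral pole levels of 0.055 and 0.097 there lay within -0.32 to 0.28. Ionotropic levels were 0.052 and 0.12, against -0.025 to 0.057 in controls. CA1 and subicular levels, at 0.34 and 0.28, lay above the controls' -0.31 to 0.11. With all 6 libraries none of the 4 had passed, at adjusted p-values of 0.952, 0.0591, 0.247 and 0.898. The camera test moved the CA1 and subicular list down there, against a positive median of 0.04, and the ventral pole list up, against a negative median of -0.03. The dentate granule list had a median of -0.17 with all 6 libraries and 16 of 18 members negative, the opposite direction. It passed downward with no filter, at 0.0348, and without control replicate 3, stress replicate 2 or stress replicate 3, at 0.00201, 0.00943 and 2.51e-05. Its median was -0.051 without control replicate 1 and -0.32 without stress replicate 3.

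**Figure D3:**
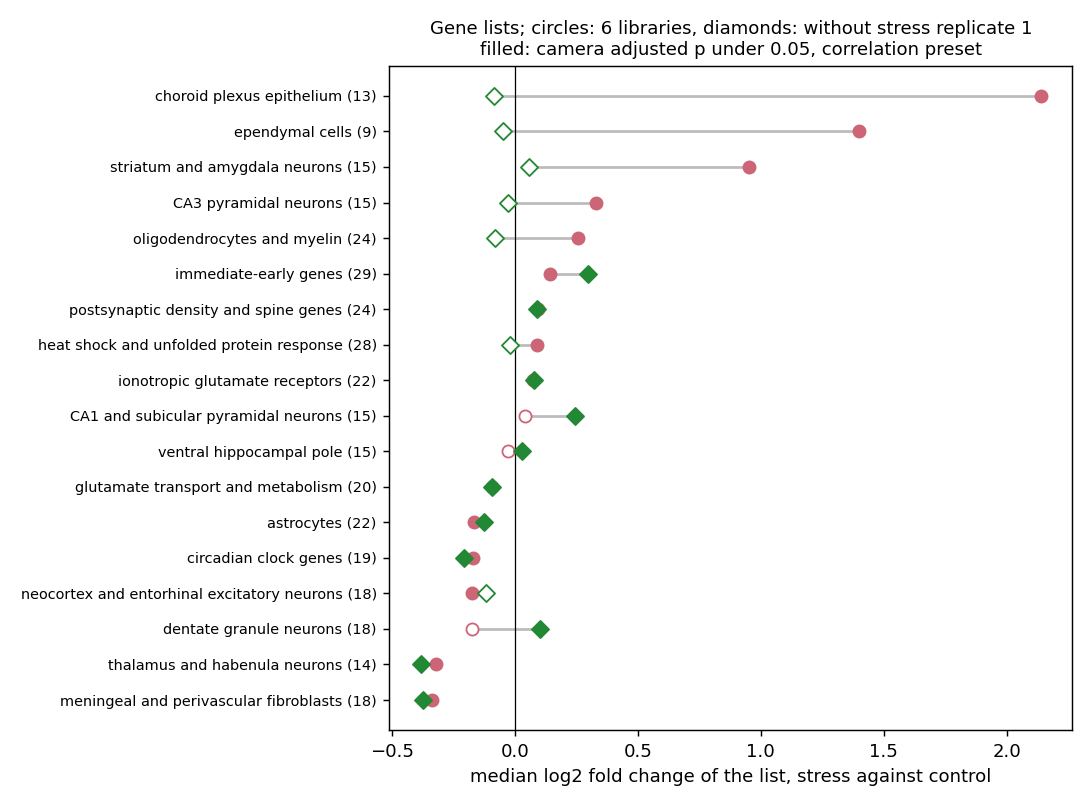
Median log2 fold change of each list that passed with 6 libraries or without stress replicate 1, with the number of tested members in brackets. Circles are 6 libraries, diamonds are without stress replicate 1, and filled markers passed camera at the preset correlation. The choroid plexus median went from 2.14 to -0.083, and the thalamus and habenula median from -0.32 to -0.38.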

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

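The tests with sample quality weights, with the offset for GC content and transcript length, and the list tests without stress replicate 1 under an estimated correlation or fry were chosen after the data had been seen. With relative log expression or upper-quartile scaling, with no filter, with the stricter filter, with a robust fit, with sample quality weights and at a threshold of 0.10, 4 genes were called lower and 0 higher. The offset gave 3 lower. DESeq2 called 38 genes higher and 68 lower, edgeR's exact test 43 and 86, and limma-voom 0 and 1. Leaving out each library in turn gave 0 to 11 genes higher and 0 to 30 lower. The count lower was 0 without control replicate 1, 2 or 3 or stress replicate 3, 26 without stress replicate 2 and 30 without stress replicate 1. The 4 genes had a negative log2 fold change in each of these fits. Members of the lists past the threshold numbered 0 with all 6 libraries, 13 with DESeq2, 18 with the exact test and 0 to 6 with 1 library left out. The cause of these differences was not tested.

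The replicate numbers did not pair the samples, since the deviations of same-numbered libraries correlated across genes at 0.14, -0.01 and 0.04. Not every library correlated best with its own number. With the replicate number as a block, 0 genes were higher, 0 were lower, 0 list members passed and 16 lists passed, the dentate granule list downward among them at 0.0409. Slc7a11 had a log2 fold change of -0.52 under the block, the CA1 and subicular list a median of 0.037 and the ventral pole list -0.034, the last 2 with a changed direction in camera.

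Slc7a11 kept its direction in each alternative. It passed with DESeq2, at -0.51, and with the exact test, at -0.51, and ran from -0.65 to -0.38 with 1 library left out. The 14 lists that passed became 0 with an estimated correlation, 1 with fry, 9 with camera on log2 CPM, and 11 to 16 with 1 library left out. Without stress replicate 1, an estimated correlation gave 0 lists and fry gave 1.

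With 1 library left out, log2 fold changes that changed sign ran from -0.46 to 3.86 for Adora2a, -0.080 to 0.57 for Cldn11, -0.083 to 3.89 for Col8a1, -0.070 to 3.17 for Dnah6, -0.079 to 0.63 for Mobp and -0.040 to 3.28 for Penk, each negative only without stress replicate 1. With sample quality weights Cldn11 was at -0.00281. Among the lists described one by one, medians whose sign, or direction in camera, changed ran from -0.052 to 0.056 for glucocorticoid-responsive, -0.085 to 0.073 for inflammatory, -0.32 to 0.10 for granule neuron, -0.027 to 0.50 for CA3, -0.089 to 0.25 for CA1 and subicular, -0.080 to 0.50 for oligodendrocyte, -0.083 to 2.69 for choroid plexus, 0.057 to 1.26 for striatum and amygdala, -0.14 to 0.030 for ventral pole, -0.076 to 0.30 for immediate-early, -0.020 to 0.15 for heat shock and -0.049 to 1.84 for ependymal genes. By fry, 13 of the 14 lists that passed did not, with adjusted p-values of 0.721 for immediate-early and 0.578 for postsynaptic genes, and on log2 CPM the immediate-early list had 0.0554. The inflammatory median was -0.012 with no filter, and the ventral pole median was -0.028 with camera on log2 CPM. Of 825 other values of named genes with all 6 libraries, 785 kept their direction and side of the threshold, and of 450 with 1 library left out, 418 did. For the lists described one by one, 130 of 168 values with all 6 libraries did, and 89 of 126 with 1 library left out, where 16 reversed. With 1 library left out, 26 of the 76 named genes moved by over 1.5 times, 25 of them without stress replicate 1. In the simulated draws, each with 200 changed genes, a 1.5-fold change was called for 45.7% of genes. This share would be lower where fewer genes change.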

Other observations

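The tests of the explanations below were chosen after the results had been seen, except those of other splits of the libraries. The fit without stress replicate 1 that some of them use was itself among the alternatives chosen before. Fibcd1, a CA1 gene, was at 19.4, 52.9 and 52.6 CPM in controls and 72.8, 82.5 and 136 CPM in stress, so each stress library lay above each control, and its adjusted p of 0.414 did not pass. Its level in stress replicate 1 went against that of its list. The list of CA1 and subicular genes was at -0.31 in control replicate 1 and -0.42 in stress replicate 1, against 0.08 to 0.34 in the other 4 libraries, on the log2 scale relative to the controls. The pituitary hormone genes Gh and Pomc were highest in stress replicate 3, at 23.7 and 30.3 CPM, against 0.392 to 10.9 and 0.764 to 3.51 CPM in the other libraries. These genes were chosen after their values were seen.

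Stress replicate 1 stood apart from the other 5 libraries on the first principal component, which held 45.5% of the variance, at 43.9 against -11.1 to -6.81. It had the highest level for 34 of the 37 tested members of the choroid plexus, ependymal and striatum and amygdala lists, 36 of which averaged at least 1 CPM in controls. Its depth of 9351979 gene counts lay within the range of the others, which argues against depth. Without it the median log2 fold change of the 37 members was -0.049, against 1.35 with it, which argues against a stress effect shared by the 3 stress libraries. Tissue from outside the dentate gyrus in this piece cannot be told apart from a response of this 1 sample, since the 34 of 37 members, Ttr at 4258 CPM and Enpp2, named after its value was seen, at 2636 CPM are the pattern itself, and the dentate granule list, at -0.75 there against -0.21 to 0.22 in the other libraries and with 16 of 18 members lowest there, goes with such tissue without excluding such a response.

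The 4 genes called lower in stress had a median log2 fold change of -1.43, and the median of their SEs was 0.16. With an offset for GC content and transcript length it was -1.45, which argues against such a trend. 3 of the 4 genes passed with the offset. Tacr3, at -1.62 against -1.65 (SE 0.19), went from an adjusted p of 0.0456 to 0.0533 at nearly the same fold. Without stress replicate 1 all 4 passed, which argues against any other tissue in that library as their cause. Whether the stress pieces held less neocortical and entorhinal tissue cannot be told apart from an effect of stress, since the median of that list without stress replicate 1 was -0.12 over members that went both ways. In the same fit the thalamus and habenula list had a median of -0.38 and the meningeal and perivascular fibroblast list -0.37. Less of either tissue was not tested for the 4 genes.

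The 10 splits of the 6 libraries are too few to judge chance. The real split gave 4 genes lower, as 1 of the 10 splits did, and at most 1 gene in one direction came from any other. For genes higher the real split gave 0, reached in 10 of 10, and the highest other was 1. For lists the real split gave 14, reached in 7 of 10, and the highest other was 21.

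Slc7a11 was lower in stress by a log2 fold change of -0.51 (SE 0.12), and without stress replicate 1 by -0.38 (SE 0.08), with both remaining stress libraries below the 3 controls, which argues against any other tissue in that library as the whole cause. Fewer astrocytes in the stress pieces may contribute and cannot be told apart from a lower level per cell. Slc7a11 lay below the lowest of the 22 tested astrocyte genes by a difference of -0.074, less than its SE, and the median of those genes was -0.16 (SD 0.14). Astrocytes were the only cell source tested for Slc7a11. The list of meningeal and perivascular fibroblast genes also moved down, with a median of -0.34, and -0.37 without stress replicate 1. An effect of stress itself stays open for both patterns.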
